A study of Homo sapiens with 22 samples.

How the data were processed

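RNA sequencing of MHCC97H cells, YTHDF1 RNA immunoprecipitation, m6A immunoprecipitation, ribosome profiling and RNA sequencing of MHCC97H tumors were used. RNA was extracted with Trizol, fragmented and primed at random, with dUTP in the second strand, per the labels' protocols. Reads were trimmed with fastp 0.18.0 and the genome build was GRCh38, per the submitters' processing notes. The aligner, the counting tool, the peak caller and any separation of mouse from human reads in the tumors are not given in the sources used here. The cell RNA table holds raw counts per gene as deposited, per the file headers. The immunoprecipitation and ribosome tables hold expected counts, partly fractional, as the authors deposited them, and these were rounded. FPKM values of cells, footprints and tumors were computed by the authors, per the file headers. The m6A table gives each peak's log2 enrichment and p-value as deposited by the authors, and the fold printed for a peak is 2 to that power. The authors' log2 change in cells equals the log2 ratio of the mean deposited FPKM for 100% of genes within 0.001.

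Libraries were grouped by the labels, with 2 per group in cells and 3 per group in tumors. Where the labels do not say that libraries came from separate cultures or animals, p-values measure only the spread between these samples, which may be technical. No batch was given in the sources used here. The labels give 12, 13 and 14 days of lenvatinib in lenvatinib libraries 1, 2 and 3, and 12 days with siYTHDF1. This run of numbers may come from filling a column, so whether the treatment times differed is open. Sorafenib was given for 12 days, per the labels. The days of sorafenib with siYTHDF1 are not given in the sources used here. No group with a control siRNA and no untreated tumor was used here, so nanoparticle delivery and the siRNA were tested together, and a knockdown of YTHDF1 mRNA was not shown in these tumors. Of the cell table's 20323 gene IDs, 20301 were found in the gene name table, and of the tumor table's 28355, 28339. RefSeq annotation of GRCh38.p14 was used only for names and for which genes are protein-coding. Replicate libraries differed by more than counting noise (chi-square per degree of freedom 2.84 in shNC and 3.92 in YTHDF1-sh2), so none was counted as a duplicate. In the ribosome table, 3 columns headed for another shRNA matched no sample and were not used, so the planned change of translational efficiency was not computed and efficiency in control cells was given in its place, a choice made after the data were seen.

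Genes in cells were tested with edgeR 4.0.16 (quasi-likelihood test, TMM scaling, filterByExpr), giving a biological coefficient of variation of 0.04. Tumor genes with an FPKM of at least 1 in at least 3 libraries were tested with limma 3.58.1 (limma-trend, robust) on log2(FPKM + 1), in 1 fit of 12 libraries. A log2 difference on this scale understates the change of genes with low values. Low FPKM values did not fall on read-sized steps, so tumor depth is unknown. The Benjamini-Hochberg adjusted p threshold was 0.05 throughout. Gene lists were tested with camera (limma) on log2 CPM with a prior count of 2, or on log2(FPKM + 1), with an inter-gene correlation of 0.01. An estimated correlation and fry, which tests whether a list's genes move one way on balance and does not compare them with other genes, were alternatives. Of 27 lists 26 had at least 3 measured genes and were tested, the erythroid markers being left out.

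For the immunoprecipitation, the ratio of CPM was taken for genes with at least 20 counts over both libraries and 1 CPM in either, with the exact conditional 95% interval. Genes at least 2-fold up with an interval above 1 were called enriched. Such intervals cover counting error only, as sequenced molecules carried no identifiers named in the sources used here. Lists were placed by the percentile of their median among 10000 random lists matched in 20 bins of expression, and in 5 bins of transcript length within each. Transcript length is that behind the deposited FPKM. Peak coordinates are on GRCh38 and count from 1. A gene's TE was its footprint FPKM over its mean RNA FPKM.

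The rule for named genes took YTHDF1 and NOTCH1, up to 10 genes per direction with the largest change among genes past the threshold with groups that do not overlap, a symbol that names no pseudogene, readthrough or unnamed locus, and at least 5 CPM or 2 FPKM in a group, and up to 4 members of each called list or list on the study's question. In single-library assays it took the 10 highest and 10 lowest. Groups, tests, lists, this rule and a first set of other settings were fixed before the data were examined. Those settings were other scalings, filters, pseudocounts, fold thresholds, DESeq2 1.42.0 for the cell counts, each library left out, and the replicate number as a block. Leaving out both siYTHDF1 tumor libraries that stand apart, library weights, scaling without mitochondrial transcripts, quantile normalization and the block in the list tests, quantile normalization for genes whose groups stand apart, quantile normalization or leaving out both libraries in the overlap of cells and tumors, and length matching in the lists of efficiency were added after the data were seen. Where 1 library was left in a cell group, it was assumed to vary like the other group.

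The methods were tested on simulated data. With 12669 genes in cells, 24 of 50 genes changed 1.25-fold, 40 of 50 changed 1.5-fold, 41 of 50 changed 2-fold and 48 of 50 changed 4-fold were called, with 10 false calls. With 11955 tumor genes, the lenvatinib comparison called 9 of 67 at 1.5-fold, 40 of 67 at 2-fold and 62 of 66 at 4-fold (6 false calls), and the average over drugs 35 of 67, 60 of 67 and 66 of 66 (4 false calls). In these simulations genes varied independently, few were changed and no tumor library stood apart, unlike in the data. Recovery and false calls in the data may therefore differ. The immunoprecipitation step called 100 of 100 genes enriched 4-fold, with 6 false calls among 12142 genes. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and R 4.3.3 were used.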

Results

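The libraries came from MHCC97H, a human hepatocellular carcinoma cell line, and from tumors that MHCC97H cells formed after implantation into the liver of mice. In cultured cells, YTHDF1, a cytoplasmic protein that binds N6-methyladenosine (m6A) in mRNA, was depleted with a short hairpin RNA (YTHDF1-sh2, n = 2) and compared with a control hairpin (shNC, n = 2) by RNA sequencing. These 4 libraries held 1.65e+07 and 2.34e+07 gene counts in shNC and 1.68e+07 and 2.13e+07 in YTHDF1-sh2. Messages bound by YTHDF1 were measured in 1 immunoprecipitate (2.64e+07 counts) and 1 input library (2.80e+07 counts), m6A sites in 1 input and 1 immunoprecipitated library, and ribosome footprints in control cells in 1 library (1.71e+07 counts). The tumors were treated from 3 weeks after implantation with lenvatinib at 10 mg/kg or sorafenib at 12.5 mg/kg, both multikinase inhibitors, alone or with lipid nanoparticles carrying an siRNA against YTHDF1 (siYTHDF1, 4 doses every 3 days), with n = 3 in each of the 4 groups. The tumor table holds FPKM without counts, so the depth behind its values is unknown.

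YTHDF1 knockdown in culture asked which messages depend on YTHDF1. YTHDF1 mRNA (ENSG00000149658) was 86.1 ± 0.97 CPM (counts scaled to library size) in shNC and 25.5 ± 1.03 in YTHDF1-sh2 cells (SD, n = 2 each), a log2 change of −1.76 (SE 0.06, edgeR adjusted p = 1.43e-11). NOTCH1 (ENSG00000148400), a Notch receptor and the gene named in the study's title, rose from 28.4 ± 0.47 to 94.6 ± 0.70 CPM, a log2 change of 1.74 (SE 0.06, edgeR adjusted p = 7.91e-12). In the authors' deposited table, YTHDF1 had a log2 change of −1.59 and NOTCH1 of 1.55. Of 12669 genes tested, 8957 passed the threshold, 4480 of them higher and 4477 lower after knockdown. When a change of at least 2-fold was also required, 1155 genes were higher and 1110 lower. The authors' deposited table lists 7177 genes with an FDR under 0.05, 3697 higher and 3480 lower. With a change of at least 2-fold as well, the authors' deposited table has 864 higher and 1269 lower.

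**Figure D1:**
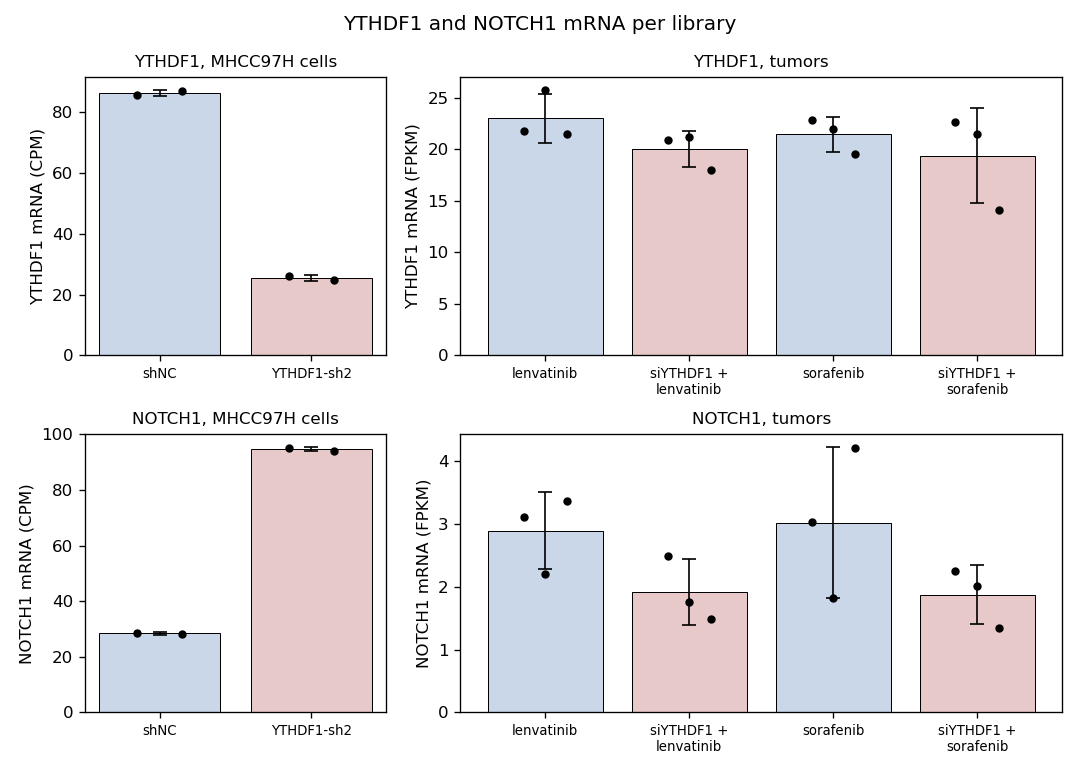
YTHDF1 and NOTCH1 mRNA in MHCC97H cells (CPM, 2 libraries per group) and in xenograft tumors (FPKM, 3 libraries per group), with bars for group means, error bars for the SD and points for libraries. In cells YTHDF1 goes from 86.1 to 25.5 and NOTCH1 from 28.4 to 94.6 CPM, whereas the groups of tumors with and without siYTHDF1 lie between 19.4 and 22.98 FPKM for YTHDF1 and between 1.87 and 3.02 FPKM for NOTCH1.

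The genes with the largest rises were nearly silent in control cells. TMEM265 had 0 counts in both shNC libraries and 263 in the YTHDF1-sh2 libraries, at least 91.6-fold higher against a floor of 3 counts over the group. CPLX2, a regulator of vesicle fusion, had 1 count against 865, a ratio of 904 with a 95% counting interval of 162 to 35729. SMIM31 had 1 count against 654, a ratio of 683 (122 to 27024), IGFBP2, a binding protein of insulin-like growth factors, 1 against 215, a ratio of 225 (39.9 to 8911), and ARC 2 against 287, a ratio of 150 (41.1 to 1244). The protocadherin PCDH7 rose by 6.42 on the log2 scale (SE 0.35), the cytokine IL11 by 6.31 (SE 0.27), the cell surface antigen CD24 by 6.05 (SE 0.37), the sterol exporter ABCG1 by 5.94 (SE 0.25) and the lipase inhibitor ANGPTL4 by 5.32 (SE 0.14). Among the largest falls, NXF2 changed by −4.71 (SE 0.21), RASGEF1A by −4.37 (SE 0.31), the glucuronosyltransferase UGT1A9 by −4.34 (SE 0.22) and NAA11 by −4.18 (SE 0.16). METTL7A and ARHGAP4 each fell by 3.86 on the log2 scale, SHC3 by 3.65, CLRN3 by 3.58, the esterase BCHE by 3.48 and FILIP1 by 3.34. NXF2 has a near-identical copy and UGT1A9 shares exons with neighboring genes, so their counts are uncertain. edgeR adjusted p-values of these genes lay at or below 9.51e-08, the value of CLRN3.

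Genes of inflammation, hypoxia, growth factor signaling and stress rose together after knockdown. Of 19 measured NF-kB targets and inflammatory cytokines, 16 rose and none fell, with a median log2 change of 1.23 (camera adjusted p = 0.000209; adjusted p = 0.504 with an estimated correlation). Prostaglandin synthase PTGS2 rose by 3.34 (SE 0.06), the chemokine CXCL5 by 5.30 (SE 0.18), the cytokine LIF by 1.97 (SE 0.08) and NFKB2 by 1.00 (SE 0.05) on the log2 scale. In the hypoxia list 18 of 27 genes rose and 3 fell (median 0.76, camera adjusted p = 0.00126; adjusted p = 0.504 with an estimated correlation), with NDRG1 at 2.60 (SE 0.05), the angiogenic factor VEGFA at 1.78 (SE 0.05) and BHLHE40 at 1.44 (SE 0.04), while CA12, PDK1 and LDHA fell. Of 19 output genes of the ERK pathway, 13 rose and 2 fell (median 0.50, camera adjusted p = 0.00318; adjusted p = 0.812 with an estimated correlation). The ERK phosphatase DUSP5 rose by 2.48 (SE 0.04), EPHA2 by 1.87 (SE 0.04), MYC by 2.41 (SE 0.07) and IER3 by 1.61 (SE 0.05), whereas ETV1 changed by −1.73. In the list of the integrated stress and unfolded protein responses, 19 of 31 genes rose and 3 fell (median 0.37, camera adjusted p = 0.0033; adjusted p = 0.504 with an estimated correlation). ATF3 rose by 4.07 (SE 0.06), the phosphatase subunit PPP1R15A by 2.14 (SE 0.05), DDIT4 by 1.92 (SE 0.06) and asparagine synthetase ASNS by 1.26 (SE 0.04).

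DNA replication genes fell and Notch target genes rose as groups. Of 35 S phase genes, 23 fell (24 adjusted over the list alone) and 8 rose, with a median log2 change of −0.28 (camera adjusted p = 0.0357; adjusted p = 0.836 with an estimated correlation). The helicase subunits MCM5 and MCM6 changed by −1.31 (SE 0.05) and −1.07 (SE 0.06) and the polymerase POLD1 by −1.30 (SE 0.06), while thymidine kinase TK1 rose by 1.33 (SE 0.05). Of 12 measured Notch targets, 8 rose and 2 fell (median 0.81, camera adjusted p = 0.0464; adjusted p = 0.747 with an estimated correlation). The repressor HES1 rose by 1.31 (SE 0.06), HES4 by 1.99 (SE 0.11), MYC by 2.41 and cyclin CCND1 by 0.84 (SE 0.04), and HEY2 changed by −1.15. MYC and CCND1 also belong to the ERK list, so the ERK and Notch target lists are not independent. The number called adjusted over the list alone was the same as over all genes for the NF-kB, hypoxia, ERK, stress response and Notch target lists.

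Of the other lists on the study's question, none passed the list test. Among 25 Notch receptors, ligands and processing genes, 11 rose and 7 fell (median 0.12, camera adjusted p = 0.453). The ligands JAG1 and JAG2 rose by 1.12 (SE 0.04) and 1.78 (SE 0.09) and the Notch transcription factor RBPJ by 0.77 (SE 0.07). Among 17 liver cancer stemness genes, 7 rose and 4 fell (median 0.69, camera adjusted p = 0.462). KLF4 rose by 1.57 (SE 0.05) and BMI1 by 1.29 (SE 0.05), and the aminopeptidase ANPEP changed by −1.06 (SE 0.05). Among 22 m6A writers, erasers and readers, 11 rose and 8 fell (9 adjusted over the list alone; median 0.17, camera adjusted p = 0.715). YTHDF2, a paralog of YTHDF1, rose by 1.02 (SE 0.05), IGF2BP1 by 0.65 (SE 0.04) and HNRNPC by 0.46 (SE 0.04).

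**Figure D2:**
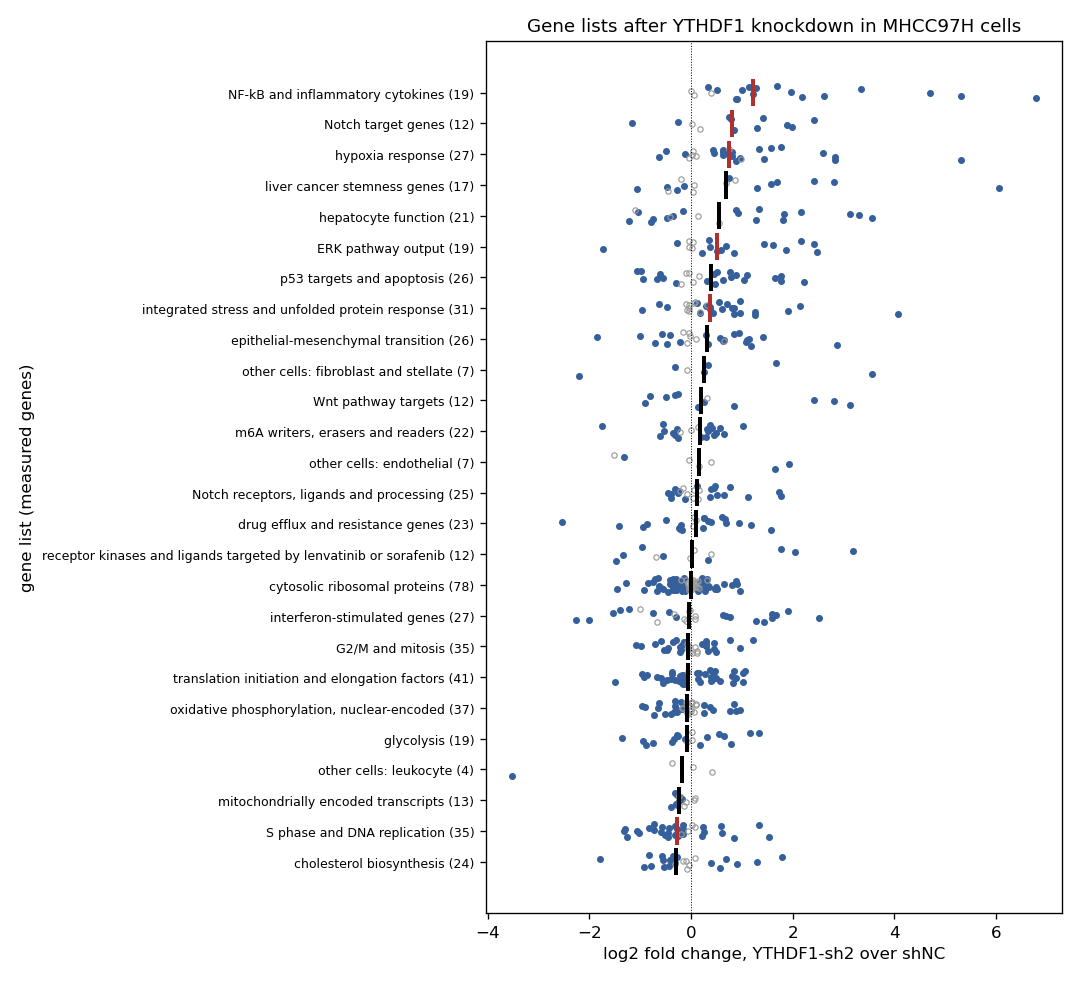
Log2 fold change (YTHDF1-sh2 over shNC, horizontal axis) of each measured gene in 26 gene lists in MHCC97H cells, with filled points for genes at an edgeR adjusted p under 0.05 and open points for the others. Vertical bars mark list medians, red for the 6 lists that passed camera's test, from −0.28 for S phase to 1.23 for NF-kB.

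Which messages carry m6A was read from the authors' peaks in control cells, called from 1 input and 1 immunoprecipitated library. The list holds 18564 peaks in 10046 genes, 8266 of them protein-coding (82.3%), with a median fold enrichment of 12.1. A single peak lay in 4547 genes and 5 or more lay in 886. NOTCH1, on the minus strand of chromosome 9 (GRCh38), held 4 peaks. The strongest spanned 136496958 to 136497207, 2525 bases from the 3′ end of the gene, with a fold of 25.96 (the authors' adjusted p = 3.78e-74). The others spanned 136495808 to 136495982 (7.17-fold), 136522918 to 136522992 (11.6-fold) and 136523168 to 136523870 (8.22-fold). YTHDF1, on the minus strand of chromosome 20, also held 4 peaks, at 63195429 to 63195478 (7.46-fold), 63196704 to 63202605 (10.8-fold), 63202731 to 63202780 (5.85-fold) and 63202956 to 63203355 (10.6-fold). The highest fold enrichments were in PITPNA (12609), FBXW4 (5397), OGFR (4284), AEBP2 (4232), MAP1LC3B (4115), TM9SF3 (3991), ZNF513 (3639), FAM72B (3390), SAE1 (3324) and CHD3 (3229), all with far less extreme p-values than that of the strongest NOTCH1 peak (the authors' adjusted p = 1.28e-11 for PITPNA). Exon and UTR positions were not analysed here.

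Messages bound by YTHDF1 were read from the ratio of CPM in the immunoprecipitate to those in the input. YTHDF1 mRNA itself was enriched 4.05-fold (95% counting interval 3.89 to 4.21), and NOTCH1 1.85-fold (1.72 to 2.00), under the 2-fold threshold. Of 12157 genes over the floor, 2246 (18.5%) were enriched at least 2-fold and 2540 were depleted at least 2-fold, around a median ratio of 1.01. The highest ratios were those of SDHAF1, an assembly factor of respiratory complex II (6.396, 5.69 to 7.21), ASDURF (5.86), SCARA3 (5.86), CCDC71 (5.69), the ubiquitin ligase RNF139 (5.46), B3GALT6 (5.43), TMEM223 (5.18), C8orf74 (5.16), POMGNT2 (5.02) and the interleukin receptor IL4R (5.02). The lowest were those of the ribosomal protein RPS29 (0.0016, 0.00141 to 0.0018), PTPRD (0.00534), the histones H4C9 (0.0167), H4C4 (0.0296) and H3C7 (0.0411), PLCG2 (0.0206), CCDC200 (0.0263), COX7B2 (0.0316), UBL5 (0.0354) and COX6C (0.0367). PTPRD had 60284 input counts but none in the RNA sequencing libraries of cells, so its ratio is not read as that of a message. Which RNA gave the input reads of PTPRD and RPS29 was not tested. There was no replicate of either library, the interval covers counting error only, and no immunoprecipitate of another antibody was used here.

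Genes of the ERK pathway lay high in the immunoprecipitate, and ribosomal protein and respiratory chain genes low. Of 19 ERK pathway genes, 10 were enriched and 0 depleted, with SPRY4 at 3.24, DUSP5 at 2.57 and SPRY2 at 2.47, and the median ratio of 2.01 lay at percentile 100 among 10000 random lists matched on input level (99.99 when matched on transcript length as well). Hepatocyte genes had a median ratio of 1.82 (percentile 96.9, or 99.1 with length) and Wnt targets 1.72 (98.8, or 94.5), each within the 95% range of random lists under 1 of the matchings. Notch receptors, ligands and processing genes (1.38, percentile 96.7, or 87.7) lay within it under both. Depletion was seen for 75 of 78 ribosomal protein genes (median ratio 0.177), 31 of 37 nuclear-encoded genes of oxidative phosphorylation (0.212) and 13 of 13 mitochondrially encoded transcripts (0.101), each at percentile 0 with either matching. S phase genes (0.624, percentile 0.69) and mitotic genes (0.529, percentile 0.07) also lay low. Of 22 m6A regulators, 6 were enriched, among them RBM15B at 4.03, RBM15 at 2.92, YTHDF3 at 2.73 and YTHDF2 at 2.31 (median ratio 1.07, percentile 77.2). Notch targets (1.26, percentile 71.3) and stemness genes (1.05, percentile 60.4) also lay within the range of random lists.

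The intersection of both assays asked whether YTHDF1 bound the methylated messages. Among 10670 genes over the floor in the RNA, immunoprecipitation and footprint libraries, 7504 (70.3%) held an m6A peak and 1712 were enriched with YTHDF1. Both applied to 1670 genes, against 1204 by chance (Fisher's exact test over genes, which are not independent replicates, odds ratio 21.3, p = 6.78e-218). YTHDF1 enrichment was found for 22.3% of genes with a peak and 1.33% of genes without one. With 0, 1, 2, 3, 4 and 5 or more peaks, the median ratio was 0.602, 0.844, 1.29, 1.63, 1.92 and 2.17. After knockdown, the 1670 genes had a median log2 change of 0.01, against −0.04 for random sets matched on expression (95% range −0.07 to −0.01). Sets matched on length as well had −0.07 (−0.10 to −0.05). Of the 1670 genes, 625 rose (605 by chance, Fisher's exact p = 0.268) and 609 fell (625 by chance, p = 0.393). Of the 7504 genes with a peak, 2808 rose (2717 by chance, Fisher's exact p = 6.57e-05) and 2791 fell (2808 by chance, p = 0.457). Fisher's test was not matched on expression. The median log2 change of the 7504 genes, −0.0063, lay within the 95% range of random sets matched on expression (−0.012 to 0.0030). It also lay within that of sets matched on length as well (−0.017 to −0.0007).

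**Figure D3:**
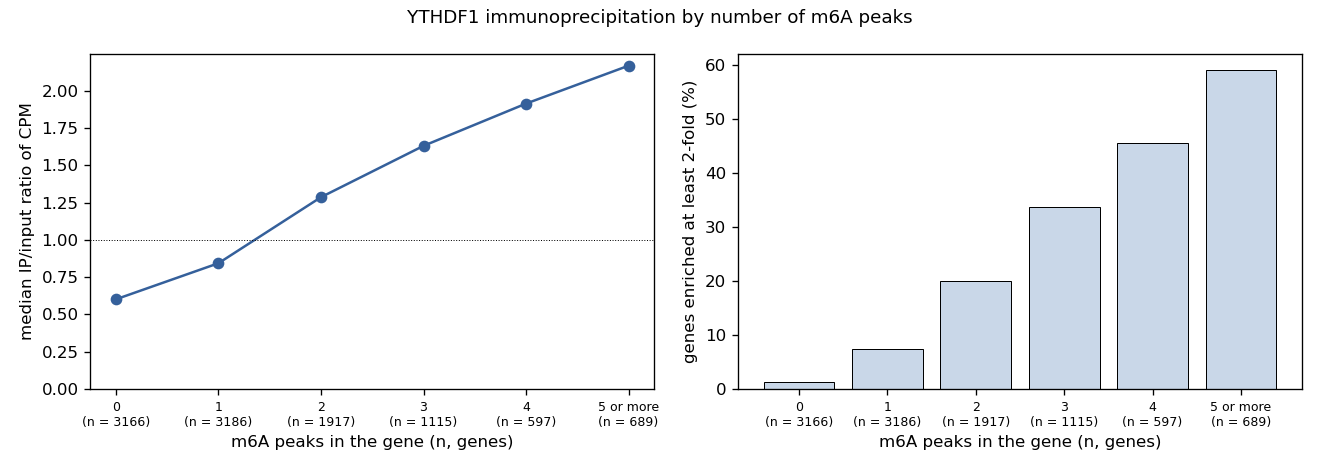
Median ratio of CPM in the YTHDF1 immunoprecipitate to the input (left) and percent of genes enriched at least 2-fold (right) by the number of m6A peaks in the gene, over 10670 genes with the number of genes per class below the axis. The median ratio goes from 0.602 with no peak to 2.17 with 5 or more peaks, and the percent enriched from 1.33 to 59.1.

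Ribosome footprints in control cells gave each gene's translational efficiency, the footprint FPKM over the mean RNA FPKM of the shNC libraries, with no replicate and no matched knockdown value. NOTCH1 lay at percentile 38.4 of all genes and YTHDF1 at percentile 73.3. The 1670 methylated and YTHDF1-enriched genes had a median log2 efficiency of −0.09, against 0.62 in random sets matched on expression (95% range 0.55 to 0.68) and 0.40 in sets matched on transcript length as well (0.33 to 0.46). By number of peaks the median was 0.95 with none and −0.17 with 5 or more. Cholesterol biosynthesis genes (median log2 efficiency 1.92), ribosomal protein genes (1.97) and nuclear-encoded oxidative phosphorylation genes (1.83) lay at percentile 100 of random lists matched on expression, and at 100, 99.95 and 99.5 when matched on transcript length as well. Mitochondrially encoded transcripts (−4.59, percentile 0 with either matching) and the receptor kinases and ligands targeted by lenvatinib or sorafenib (−0.75, percentile 0.37, or 0.51 with length) lay lowest. Whether the library recovered footprints from mitochondria as it did from the cytosol was not tested, so the mitochondrial value is not read as low translation. Efficiency was lower in longer transcripts, with a Spearman correlation of −0.34 across genes, which are not independent replicates.

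In tumors, the comparisons with siYTHDF1 asked what its delivery added to each drug. With lenvatinib, YTHDF1 was 22.98 ± 2.36 FPKM without and 20.01 ± 1.72 with siYTHDF1 (SD, n = 3 each), a log2 difference of −0.19 (SE 0.21, limma adjusted p = 0.702) on the scale of log2(FPKM + 1). NOTCH1 was 2.89 ± 0.62 and 1.91 ± 0.52 FPKM, a difference of −0.42 (SE 0.22, limma adjusted p = 0.451). Of 11955 genes tested with limma, 0 passed the threshold, while 1447 had an unadjusted p under 0.05, 531 higher and 916 lower with siYTHDF1. The median of all genes was −0.08, and it was 0.02 without siYTHDF1 with lenvatinib 3. After quantile normalization 0 genes passed, and of 2303 with an unadjusted p under 0.05, 1154 were higher and 1149 lower. Without both siYTHDF1 libraries that stand apart, siYTHDF1 with lenvatinib 3 and siYTHDF1 with sorafenib 3, the split was 1000 higher and 504 lower of 1504. Without lenvatinib library 3, or without siYTHDF1 with lenvatinib 1, 1 gene passed.

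Mitochondrially encoded transcripts were higher with siYTHDF1 and lenvatinib than with lenvatinib alone. All 13 had a positive log2 difference, 7 of them passing when adjusted over the list alone, and the median was 1.03 (camera adjusted p = 9.35e-09; adjusted p = 0.971 with an estimated correlation). MT-ATP6 differed by 1.12 (SE 0.38), MT-CYB by 1.12 (SE 0.39) and MT-ND2 by 1.11 (SE 0.41). In library 3 of this group they took 58.0% of all FPKM, against 21.2% to 32.6% in the 11 other tumors, and the median difference was 0.09 after quantile normalization (camera adjusted p = 0.187). Quantile normalization gives all libraries the same highest values, and these transcripts are among the highest. It can remove a shared difference of theirs by construction, so it does not decide on this list. Genes of epithelial-mesenchymal transition were lower as a group (median −0.48, or −0.28 without both libraries that stand apart, camera adjusted p = 0.00139; adjusted p = 0.971 with an estimated correlation), with the TGF-beta receptor TGFBR2 at −0.87 (SE 0.33), fibronectin FN1 at −0.98 (SE 0.38) and N-cadherin CDH2 at −0.81 (SE 0.33). Notch receptors, ligands and processing genes (median −0.35, camera adjusted p = 0.002) and glycolysis genes (−0.36, 0.0265) were also lower, and ribosomal protein genes higher (0.13, 0.00588), each with adjusted p = 0.971 with an estimated correlation. Without both libraries that stand apart the Notch list was at −0.18 and glycolysis at −0.20. NOTCH2 differed by −0.79 (SE 0.26), MAML2 by −0.56 (SE 0.21) and the glycolytic kinase PGK1 by −1.07 (SE 0.42). Of the members of these 4 lists, 0 passed when adjusted over the list alone. The Notch target list was not called (median 0.07). Its members HES1 and HES4 differed by 0.71 (SE 0.22) and 0.56 (SE 0.35), and SNAI2 and CCND1 by −0.57 (SE 0.32) and −0.30 (SE 0.21). Fibroblast markers had a median of −0.42 in the same comparison (3 measured, camera adjusted p = 0.486). When the libraries of this comparison were divided in other ways, camera called a median of 7 lists, against the 5 found.

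With sorafenib, YTHDF1 was 21.5 ± 1.69 FPKM without and 19.4 ± 4.65 with siYTHDF1 (SD, n = 3 each), a log2 difference of −0.16 (SE 0.21, limma adjusted p = 0.800). NOTCH1 was 3.02 ± 1.20 and 1.87 ± 0.47 FPKM, a difference of −0.45 (SE 0.22, limma adjusted p = 0.591). Of 11955 genes tested with limma, 0 passed the threshold and 1005 had an unadjusted p under 0.05, 162 higher and 843 lower, around a median of all genes of −0.14. Quantile normalization moved that median to −0.02 and the split to 480 higher and 489 lower of 969, with 0 genes passing. Without sorafenib library 1, 9 genes passed, and without sorafenib library 2, 3 genes. Library 3 of siYTHDF1 with sorafenib stood apart, with the lowest FPKM total (174906 against 225279 to 376391) and 8.07% of FPKM in pseudogenes, and without it the median of all genes was −0.0014. Without it and siYTHDF1 with lenvatinib 3, 2 genes passed and the split at an unadjusted p under 0.05 was 1253 higher and 1172 lower of 2425.

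In sorafenib tumors 9 lists passed camera's test, given here with the median log2 difference and, in brackets, that median relative to all genes. When the libraries of this comparison were divided in other ways, camera called a median of 7 lists. Genes of epithelial-mesenchymal transition were lower with siYTHDF1 (−0.68 [−0.54], camera adjusted p = 2.34e-09; adjusted p = 0.569 with an estimated correlation), 9 of 23 passing when adjusted over the list alone and 0 over all genes. The matrix proteins THBS1 and CCN1 differed by −1.53 (SE 0.39) and −1.01 (SE 0.22), the growth factor TGFB1 by −0.94 (SE 0.23) and the receptor kinase AXL by −1.18 (SE 0.33). Fibroblast markers had a median of −0.54 in these tumors (3 measured, camera adjusted p = 0.364). NF-kB targets and cytokines (−0.77 [−0.63], camera adjusted p = 0.000544), cholesterol biosynthesis genes (−0.38 [−0.24], 0.000544) and Notch receptors, ligands and processing genes (−0.31 [−0.17], 0.000483) were lower too, each with adjusted p = 0.794 with an estimated correlation. Without both libraries that stand apart the NF-kB list was at −1.20 and the Notch list at −0.18, while leukocyte markers had a median of −1.05 with all libraries (3 measured, camera adjusted p = 0.75). The fringe enzyme LFNG differed by −0.81 (SE 0.18) and was the 1 member of these 3 lists that passed when adjusted over the list alone, while TNFAIP3 differed by −0.89 (SE 0.33) and the sterol sensor INSIG1 by −0.77 (SE 0.24). Ribosomal protein genes (0.13 [0.27], camera adjusted p = 6.73e-12), nuclear-encoded oxidative phosphorylation genes (0.12 [0.26], 6.46e-09) and hepatocyte genes (0.29 [0.43], 0.00092) were higher, each with adjusted p = 0.794 with an estimated correlation, and without both libraries they were at 0.27, 0.29 and 0.55. Of 18 hepatocyte genes 15 had a positive difference, while the protease inhibitor SERPINA1 was at −2.53 (SE 0.75) and the transcription factor HNF4A at −0.37 (SE 0.17). Among the positive ones, TTR (0.95 ± 0.66 FPKM without and 1.61 ± 0.74 with siYTHDF1) and APOB (0.84 ± 0.48 and 1.44 ± 0.82) lay near the filter of 1 FPKM. Reads from the mouse liver were not tested as a source. S phase genes had a median of 0.01 [0.15] (camera adjusted p = 0.00656; adjusted p = 0.846 with an estimated correlation), or 0.25 without both libraries. The stress response list (0.03 [0.17], mean −0.01, camera adjusted p = 0.0474; adjusted p = 0.794 with an estimated correlation) was not called after quantile normalization (0.109) or without both libraries (0.487). Notch targets were not called (−0.06 [0.08]). Among them SOX9 differed by −0.84 (SE 0.25), MYC by −0.59 (SE 0.22), SNAI2 by −0.50 (SE 0.32) and HEY1 by −0.23 (SE 0.24).

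Averaged over both drugs, siYTHDF1 was compared in 6 tumors against 6. LBH, a transcription cofactor (ENSG00000213626), was 4.50 ± 0.71 FPKM with lenvatinib and 2.32 ± 0.91 with siYTHDF1 added, and 5.78 ± 0.89 with sorafenib and 1.43 ± 0.50 with siYTHDF1 added (SD, n = 3 each), an average log2 change of −1.13 (SE 0.15, limma adjusted p = 0.0237). PET100P1 (ENSG00000283390), a pseudogene that may share reads with PET100, rose by 0.89 (SE 0.13, limma adjusted p = 0.0333) and, as a pseudogene, lies outside the rule for named genes. It was chosen after its values were seen, because so few genes passed. In both genes the groups did not overlap within either drug. YTHDF1 differed by −0.18 (SE 0.15, limma adjusted p = 0.538) and NOTCH1 by −0.44 (SE 0.16, limma adjusted p = 0.201). LBH and PET100P1 were the 2 of 11955 genes that passed, while 2094 had an unadjusted p under 0.05, 364 higher and 1730 lower, around a median of all genes of −0.10. After quantile normalization 0 genes passed by limma and the split was 1120 higher and 1295 lower of 2415. Without both libraries that stand apart it was 1655 higher and 1283 lower of 2938, around a median of all genes of 0.02. By limma 0 genes passed without lenvatinib 1, siYTHDF1 with lenvatinib 3, sorafenib 2, or siYTHDF1 with sorafenib 2 or 3, and LBH but not PET100P1 passed without siYTHDF1 with lenvatinib 2, sorafenib 1 or sorafenib 3. Leaving out lenvatinib 2, siYTHDF1 with lenvatinib 1 or siYTHDF1 with sorafenib 1 gave 8, 6 and 4 genes. In 680 genes the groups stood apart the same way within both drugs, 600 lower and 80 higher with siYTHDF1, which is 5.69% of genes. By chance 0.5% would do so on average over groupings, but genes are not independent, so a single grouping can lie far from that average. This count was not set against other splits of the libraries. After quantile normalization 500 genes stood apart the same way, 269 lower and 231 higher.

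Genes of epithelial-mesenchymal transition were lower with siYTHDF1 over both drugs (median −0.53, camera adjusted p = 2.27e-08; adjusted p = 0.728 with an estimated correlation), all 23 being negative and 15 passing when adjusted over the list alone, against 0 over all genes. Fibronectin FN1 differed by −1.05 (SE 0.27) and TGFB1 by −0.75 (SE 0.16). Fibroblast markers had a median of −0.39 (3 measured, camera adjusted p = 0.322). Notch receptors, ligands and processing genes (median −0.30, or −0.18 without both libraries that stand apart, camera adjusted p = 3.09e-05; adjusted p = 0.767 with an estimated correlation) had 9 of 24 lower when adjusted over the list alone. Among them were NOTCH2 at −0.76 (SE 0.18), RBPJ at −0.43 (SE 0.12) and ADAM10 at −0.50 (SE 0.15). Notch targets were not called (median −0.02, camera adjusted p = 0.498). Of these HES1 differed by 0.36 (SE 0.16), SNAI2 by −0.53 (SE 0.23), SOX9 by −0.37 (SE 0.18) and MYC by −0.31 (SE 0.16). NF-kB targets and cytokines (−0.63, camera adjusted p = 0.00122) and glycolysis genes (−0.35, 0.0206) were lower, each with adjusted p = 0.767 with an estimated correlation and 1 member passing when adjusted over the list alone. Leukocyte markers had a median of −0.66 (3 measured, camera adjusted p = 0.498). RELB differed by −0.62 (SE 0.17) and SLC16A1 by −0.53 (SE 0.14). Mitochondrially encoded transcripts (0.55, camera adjusted p = 1.26e-07), ribosomal protein genes (0.10, 9.82e-09), nuclear-encoded oxidative phosphorylation genes (0.10, 7.05e-05), hepatocyte genes (0.07, 0.0206; HNF4A at −0.34, SE 0.12) and S phase genes (0.04, 0.0206) were higher, each with adjusted p = 0.767 with an estimated correlation. Without both libraries these 5 lists were at 0.37, 0.19, 0.20, 0.29 and 0.20, and hepatocyte genes (camera adjusted p = 0.07) and glycolysis genes (−0.10, 0.0929) were not called. With all libraries, the S phase median was 0.15 relative to all genes. Its members E2F1 and RFC4 differed by 0.28 (SE 0.17) and 0.25 (SE 0.15), but RPA1 and TYMS by −0.48 (SE 0.22) and −0.38 (SE 0.25). Of oxidative phosphorylation genes, COX5B, NDUFV2 and NDUFA2 were at 0.49, 0.44 and 0.36, but SDHC was at −0.53 (SE 0.18). After quantile normalization the mitochondrial list (0.06, camera adjusted p = 0.276) and the hepatocyte list (0.18, 0.101) were not called. For the mitochondrial list that setting does not decide, since it equalizes the highest values of all libraries. When the 12 libraries were divided in other ways within the drugs, camera called a median of 8 lists.

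Whether the effect of siYTHDF1 differed between the drugs was tested as the lenvatinib effect minus the sorafenib effect. YTHDF1 differed by −0.02 (SE 0.30) and NOTCH1 by 0.03 (SE 0.31), and of 11955 genes tested with limma 0 passed, with 565 at an unadjusted p under 0.05 (473 higher, 92 lower). Of 100 splits of the libraries within the drugs, the real one included, 32 gave as many, so chance cannot be excluded for the 565. Without lenvatinib library 3, 1 gene passed. After quantile normalization 0 passed and the split was 495 higher and 306 lower of 801. Without both libraries that stand apart, and without quantile normalization, it was 604 and 357 of 961. Cholesterol biosynthesis genes had the more positive effect with lenvatinib (median difference 0.31, camera adjusted p = 0.0237; adjusted p = 0.987 with an estimated correlation, here and for both lists that follow), INSIG1 by 1.15 (SE 0.34) and HSD17B7 by 0.58 (SE 0.19). Nuclear-encoded oxidative phosphorylation genes had the lower one (−0.15, 0.0134). Mitochondrially encoded transcripts differed by 0.92 (0.000425), and not past the threshold after quantile normalization (0.13) or without both libraries that stand apart (0.20), each with a camera adjusted p = 0.409. Of these settings, quantile normalization does not decide here, since it equalizes the highest values of all libraries.

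Sorafenib tumors were compared with lenvatinib tumors without siYTHDF1 as well. Hypoxia genes were lower with sorafenib (median −0.43, camera adjusted p = 2.44e-11; adjusted p = 0.913 with an estimated correlation, here and for the 9 other lists called), with ANGPTL4 at −1.68 (SE 0.62), ANKRD37 at −0.68 (SE 0.31) and the vasodilator peptide ADM at −0.97 (SE 0.32). Ribosomal protein genes (−0.19, 3.05e-09), NF-kB targets and cytokines (−0.23, 0.00653) and oxidative phosphorylation genes (−0.07, 0.0129) were lower, and S phase (0.18, 0.00187), mitotic (0.17, 0.0162) and cholesterol biosynthesis genes (0.20, 0.0186) higher. Leukocyte markers had a median of −0.35 (3 measured, camera adjusted p = 0.0929). The replication factor CDC6 differed by 0.59 (SE 0.23) and the mitotic protein PRC1 by 0.62 (SE 0.26). Glycolysis genes (−0.26, 0.0113), mitochondrially encoded transcripts (−0.20, 0.0162) and Notch targets (−0.17, 0.0452) were lower too, and not called after quantile normalization (0.186, 0.604 and 0.171). For the mitochondrial transcripts that setting does not decide, since it equalizes the highest values of all libraries. YTHDF1 differed by −0.09 (SE 0.21) and NOTCH1 by 0.02 (SE 0.22). Of 11955 genes tested with limma 0 passed and 468 had an unadjusted p under 0.05, 274 higher and 194 lower, or 339 and 369 of 708 after quantile normalization, again with 0 passing. Of 10 splits of these libraries, the real one included, 2 gave as many as the 468, so chance cannot be excluded for that count. Without sorafenib library 1, 11 genes passed, and 1 without lenvatinib library 3. When the libraries of this comparison were divided in other ways, camera called a median of 7 lists, against the 10 found.

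Cells and tumors were set side by side over 10730 genes tested in both. YTHDF1 itself fell by 1.76 in cells and differed by −0.18 in tumors (limma adjusted p = 0.538), so a loss of YTHDF1 mRNA was measured in cells and not shown in tumors. NF-kB targets and cytokines rose in cells (median 1.23) and were lower in tumors with siYTHDF1 (−0.63), by camera's test, with adjusted p = 0.504 in cells and adjusted p = 0.767 in tumors with an estimated correlation. Leukocyte markers had a median of −0.66 in the same tumors. NOTCH1 rose by 1.74 in cells against a difference of −0.44 in tumors. LBH, chosen after its tumor values were seen, passed in both and in opposite directions, rising by 3.49 in cells (SE 0.20, edgeR adjusted p = 1.74e-09) and differing by −1.13 in tumors. Passing in both in 1 direction was found for 0 genes by edgeR and limma, with 3992 rising and 3860 falling in cells against 0 and 1 in tumors. At an unadjusted p under 0.05, 64 genes were higher in both (79.7 by chance, Fisher's exact p = 0.0256) and 512 lower in both (619 by chance, Fisher's exact p = 2.87e-09). After quantile normalization of the tumors these were 285 (347 by chance) and 398 (465 by chance), and without both libraries that stand apart 417 (552 by chance) and 335 (455 by chance). Across genes, which are not independent replicates, the log2 changes had a Spearman correlation of −0.12, or −0.11 and −0.14 in these settings.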

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

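All splits of the libraries, the tests of length and expression together and the question of a single shRNA were chosen only after the results were seen. The tests of NOTCH1 across settings, of length over peak numbers and of the outlying library were written before their results.

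Between the drugs, the median effect of siYTHDF1 with lenvatinib minus that with sorafenib was 0.31 for cholesterol biosynthesis genes and −0.15 for nuclear-encoded oxidative phosphorylation genes, by camera's test of the difference. For mitochondrially encoded transcripts it was 0.92 by the same test, and 0.13 after quantile normalization or 0.20 without both siYTHDF1 libraries that stand apart, each with a camera adjusted p = 0.409. Quantile normalization equalizes the highest values of all libraries, so it does not decide for these transcripts. None of the 3 lists was called with an estimated correlation (adjusted p = 0.987 for each). Over 100 splits of the libraries within the drugs, the real one included, 93 called as many lists as the 3 found here and the highest other split called 14, so chance cannot be excluded for the number of lists.

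Mitochondrially encoded transcripts were higher with siYTHDF1 and lenvatinib by a median log2 of 1.03. A candidate technical cause is library 3 of that group, in which they took 58.0% of FPKM. Without it and siYTHDF1 with sorafenib 3, the median was 0.53, above the bound of 0.5 set beforehand by less than the members' median SE of 0.40, so a single library cannot be told apart from an effect of siYTHDF1. That comparison with the SE was added after the value was seen. RNA quality and mouse reads were not tested, and stay open beside a biological difference.

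NOTCH1 mRNA was higher in knockdown cells. Scaling, filtering, tool and single libraries are argued against, since the lowest log2 change over 11 settings was 1.72 and NOTCH1 passed in all 11. The number of shRNAs against YTHDF1 in this RNA sequencing was 1, so an effect of this shRNA or of the cells that carry it cannot be told apart from an effect of YTHDF1. Higher NOTCH1 mRNA may therefore follow YTHDF1 loss or this shRNA alone.

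Messages with an m6A peak had a median log2 ratio of 0.28 in the YTHDF1 immunoprecipitate, outside the range of −0.05 to −0.01 of random sets matched on expression and length, which argues against those properties as the whole cause. Within each of 5 classes of length, genes with 3 or more peaks exceeded genes with none by at least 1.14, which argues against length alone for the trend over peak numbers. Binding by the antibody without YTHDF1 was not tested. With that open, preferential binding of methylated messages is a hypothesis.

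The counts of changed genes in tumors were set against other splits of the same libraries. Averaged over both drugs, 2 of 100 splits, the real one included, gave as many as the 2 genes found, and the highest other split gave 6. That share lies under 0.05, but the test was among several chosen after the results and was not corrected for their number, so chance is not excluded for the count. A split with several times the real count may point to a structure of the samples, which was not tested, and neither gene passed after quantile normalization or in 5 of the fits with a library left out. For the 9 lists called in that comparison, 40 of 100 splits gave as many and the highest other gave 16, so chance cannot be excluded. For the difference between the drugs 0 genes were found, which all 100 of 100 splits reach by construction, so this count tests nothing (the highest other gave 6). With library weights 3480 genes were called, 8 of 100 splits gave as many and the highest other gave 5120, so chance cannot be excluded. For lenvatinib, sorafenib and the comparison of both drugs, the 10 splits are too few for a share under 0.05, with 0 genes found in each and a highest other of 1, and with 5, 9 and 10 lists found and a highest other of 13, 12 and 10. As many lists were called in 9, 2 and 4 of the 10 splits, and the other splits called a median of 7 in each comparison. As many genes at an unadjusted p under 0.05 were found in 1, 2 and 2 of the 10 splits. For the average it was 2 of 100 and for the difference 32 of 100, the real one included.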

How the results depend on the processing

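Library weights, quantile normalization and the block in list tests, quantile normalization for genes whose groups stand apart, other tumor settings in the overlap with cells, length matching for efficiency, efficiency in control cells, scaling without mitochondrial transcripts and leaving out both siYTHDF1 libraries that stand apart were alternatives chosen after seeing the data. No gene or list called here reversed. The median of all genes with lenvatinib turned from −0.08 to 0.02 without siYTHDF1 with lenvatinib 3, and the averaged one from −0.10 to 0.02 without both libraries that stand apart. With library weights the medians were 0.02 with lenvatinib, 0.0067 with sorafenib and 0.02 in the average. All 477 alternative values of 53 named genes in cells kept their side of the threshold, as did 3368 of tumor genes. Another 92 tumor values became called, all with library weights, and 22 lost a call (LBH and PET100P1). Values of genes called in neither fit were counted as kept whatever their direction, so these counts do not show a kept direction for them. In cells, leaving out a library gave 8192 to 8775 genes, and 2265 were at least 2-fold as well. For lenvatinib, 1 gene passed with a 5 FPKM filter and 1 in a fit of only those groups, 0 to 1 with a library left out, and 564 with weights. For sorafenib, 0 to 9 passed with a library left out, 2 without both libraries and 3168 with weights. Averaged over both drugs, 12 passed with the 5 FPKM filter, 0 without a filter, with quantile normalization, without both libraries and with mitochondrial transcripts removed, 1 at least 2-fold, 3480 with weights and 0 to 8 with a library left out. The difference between drugs had 0 to 1 with a library left out and 129 with weights, and the comparison of drugs 0 to 11 with a library left out. With the scaling and libraries of the report, an estimated correlation gave 0 lists in each of the 6 comparisons, against 1 with sorafenib after quantile normalization. Fry gave 20 in cells (11 with the block), 1 in the average (0 with the block, 3 after quantile normalization, 4 without both libraries) and 0 in the others, except with sorafenib 1 after quantile normalization and 3 without both libraries. Without both libraries, camera called 8 lists with lenvatinib (5 with all libraries), 12 with sorafenib (9), 11 in the average (9) and 8 for the difference between drugs (3), and an estimated correlation called 0 of them. Those added were S phase, mitosis and NF-kB with lenvatinib, mitosis, hypoxia, ERK output and mitochondrial transcripts with sorafenib, mitosis, hypoxia, ERK output and cholesterol genes in the average, and ribosomal, translation, epithelial-mesenchymal, efflux, NF-kB and hepatocyte genes for the difference. The number of genes enriched in the YTHDF1 immunoprecipitate was 3781 at 1.5-fold and 161 at 4-fold. The stricter methylated and bound set, with a fold of at least 4 in both assays, held 66. Its m6A bound still kept 7504 genes, so only the bound on the immunoprecipitate, with 67 genes, made it smaller. At an unadjusted p, 576 genes moved the same way in cells and tumors (683 with quantile normalization, 752 without both libraries). The causes were not tested, except that stricter thresholds leave fewer genes by construction. Same-numbered tumors had a median correlation of deviations of 0.04 (−0.29 to 0.28, 18 pairs). Tumors with different numbers had one of −0.02 (−0.40 to 0.27, 36 pairs), so no pairing by number was seen. Same-numbered cell libraries had −0.02, but with 2 libraries per group these values mirror each other, so pairing in cells cannot be told. With the replicate block 9453 genes were called in cells and 1 in the average over drugs. Camera with the block called 9 lists in cells (6 without it) and 10 with sorafenib (9 without it). The change of translational efficiency and its 4 alternatives were not run, and DESeq2 was not run on FPKM. With tumor depth unknown, no floor can be given for low genes.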

Other observations

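The post hoc set here is the replication-dependent histone genes, chosen after the lowest immunoprecipitation ratios were seen. Of 59 such genes, which make short messages without a poly(A) tail, 58 were depleted at least 2-fold, with a median ratio of 0.13. No test is given for a set chosen from these ratios, and short messages had low ratios in general, with a median of 0.425 in the 2385 genes of the shortest length class. PTPRD had 60284 counts in the input, 304 in the immunoprecipitate and 0 in all 4 RNA sequencing libraries of cells. Hypoxia genes had high translational efficiency in control cells (median log2 1.58, percentile 99.7, or 99.9 when matched on transcript length as well). Stress response genes (0.29) lay within the 95% range of random lists matched on expression (percentile 3.5) and below it when matched on length as well (1.74).

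In knockdown cells several lists that were not called held genes with large changes in both directions. Of 21 hepatocyte genes, 10 rose and 7 fell (median 0.55, camera adjusted p = 0.59), with ASS1 at 3.56 (SE 0.12) and AMBP at −1.22 (SE 0.13). Of 12 Wnt targets, 6 rose and 5 fell (0.20, 0.59), with DKK1 at 3.14 (SE 0.05). Of 23 drug efflux and resistance genes, 11 rose and 9 fell (0.10, 0.597), with the transporter ABCB1 at 1.58 (SE 0.09) and the receptor ERBB3 at −2.54 (SE 0.08). Of 26 p53 targets, 14 rose (15 adjusted over the list alone) and 7 fell (0.39, 0.216), with CDKN1A at 1.65 (SE 0.05) and GDF15 at 1.77 (SE 0.06). Of 26 genes of epithelial-mesenchymal transition, 13 rose and 7 fell (0.32, 0.332), with CCN1 at 2.87 (SE 0.07) and SPARC at −1.85 (SE 0.26). Of 24 cholesterol biosynthesis genes, 6 rose and 12 fell (−0.29, 0.529), with SQLE at 1.78 (SE 0.06).

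The remaining lists in cells were not called without the replicate block. With the block camera called 9 lists in cells, against 6 without it. Mitochondrially encoded transcripts had a median of −0.23 (8 of 13 fell, camera adjusted p = 0.0672), oxidative phosphorylation −0.08 (0.49), ribosomal proteins −0.01 (0.529), mitosis −0.05 (0.715), glycolysis −0.08 (0.783) and receptor kinases and ligands 0.03 (0.774). Markers of endothelial cells had a median of 0.15 (0.687), of fibroblasts 0.26 (0.715) and of leukocytes −0.17 (0.774). Median, mean and test differed in sign for interferon-stimulated genes (median −0.04, mean 0.08, test up, camera adjusted p = 0.867) and translation factors (−0.05, 0.03, up, 0.902). In tumors they differed with lenvatinib for mitosis, stress response, hepatocyte and cholesterol genes, and with sorafenib for translation, mitosis, stress response, efflux, interferon and endothelial genes, the test pointing up in each. For the difference between drugs they differed for Notch receptors, stemness, m6A, S phase, interferon, fibroblast and leukocyte lists, and between the drugs for Notch receptors, stemness and p53 targets.

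Lists not called in the average over drugs had these median log2 differences. Hypoxia genes were at −0.35, m6A regulators at −0.18 and cholesterol biosynthesis at −0.21, each with a camera adjusted p = 0.0526. Wnt targets were at −0.24 (0.096), ERK output at −0.21 (0.313), p53 targets at −0.19 (0.379), stemness genes at −0.19 (0.729), translation factors at −0.14 (0.498), efflux and resistance genes at −0.09 (0.52) and receptor kinases at −0.17 (0.546). Fibroblast markers were at −0.39 (0.322), leukocyte markers at −0.66 (0.498) and endothelial markers at −0.18 (0.546). The test pointed up against a negative median for mitosis (−0.04, 0.088), stress response (−0.08, 0.212), Notch targets (−0.02, 0.498) and interferon-stimulated genes (−0.08, 0.498).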
